A study of Mus musculus with 88 samples.

How the data were processed

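The series holds 88 mouse samples, of which 26 were RNA-seq libraries and 62 were bisulfite sequencing samples. The RNA-seq libraries were analysed; the bisulfite samples were not analysed here. Embryonic stem cell (ESC) lines came from a pair of crosses. In the B6 cross (129X1/SvJ and C57BL6), 16 libraries covered 4 media, both sexes and 2 lines for each medium and sex. In the MSM cross (129X1/SvJ and MSM/Ms), 10 libraries covered 4 ESC lines in 2i (XX lines 15 and 2, XY lines 20 and 23), 2 ESC lines in serum (labelled S, XX line 8 and XY line 12), 1 2i line moved to serum (2i-S, XX line 15), 2 libraries of mouse embryonic fibroblasts (MEFs) and 1 MEF library derived from 2i ESC line 15 (2i MEF). The media were 2i (an inhibitor of MEK, the kinase that activates ERK, with an inhibitor of GSK3, which raises Wnt/beta-catenin signalling), t2i (2i with the MEK inhibitor titrated down), a2i (alternative 2i, with a Src inhibitor in place of the MEK inhibitor) and serum with the cytokine LIF. Libraries were treated as separate lines. Line 15 of the MSM cross supplied 3 of them (2i, 2i-S and 2i MEF), so the comparison of 2i-S with 2i sets a culture against a group that holds its parent line, and no fit had a term for this. Per the labels, the ESC lines derived in each medium were at passage 3, while the 2i-S culture was passaged further. The labels also give the 2i MEF more passages than the MEFs. Passage thus cannot be told apart from medium history or origin in these comparisons. The titles and descriptions of the 2 MEF libraries give conflicting sexes, so the MEFs carried no sex in any fit.

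The values are gene-level RPKM, deposited as 1 table by the authors, who per the labels made stranded mRNA libraries. Per the submitters' processing notes, cutadapt 1.9.1, TopHat2 2.1.0, Bowtie2 2.2.5 and Cufflinks 2.2.1 were used with the mm10 build, and which tool made the RNA values is not given in the sources used here. The annotation release is likewise not given in the sources used here. The table lists 21942 loci with mouse Ensembl identifiers, gene names and mm10 positions. Of the identifiers, 40 stood at more than 1 locus, and these loci were kept apart; a gene name stands for its locus with the highest mean RPKM. All 183 Y-linked and 13 mitochondrial loci read 0 in the 10 MSM-cross libraries, MEFs and XY lines included, so Y-linked and mitochondrial genes were compared in the B6 cross only. RPKM summed to between 624274 and 934309 per library, and 11234 to 12558 genes reached 1 RPKM. Read counts were not used here, so absolute depth is unknown. Relative depth, read from the step between the lowest values of each library, ran from 0.77 (2i XY line 6, the B6 cross) to 1.87 times (S XX line 8, the MSM cross) that of 2i XX line 3 of the B6 cross. The modal step held 22.79% to 42.47% of the low genes of a library, so these ratios are approximate.

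Values were taken to log2 after a pseudocount of 1 RPKM, with no further scaling, and genes with at least 1 RPKM in at least 2 libraries of a fit were kept. Fold changes on this scale understate the change of genes near or below 1 RPKM, and where all libraries of a group are listed at 0 no fold is given, except within the sex by medium differences of Ddx3y and the list medians. Fits used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), and adjusted p-values are Benjamini-Hochberg values over the genes of a fit, called under 0.05. The B6-cross fit held 8 group means (medium by sex, 8 residual degrees of freedom), and medium comparisons are the mean of the XX and XY differences. The MSM-cross fit held 1 mean per culture group and a term for XX among the ESCs (4 residual degrees of freedom), and the lone 2i-S and 2i MEF libraries were assumed to vary like the other groups. The 2i against serum effect was compared between the crosses in a fit of 14 libraries with a sex term in each cross (8 residual degrees of freedom). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

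Comparisons, tests and 21 gene lists (319 genes, 9 of them without a match in the table) were fixed before the data were examined. The lists were core, naive, and formative and primed pluripotency genes, ERK pathway targets, Wnt targets, YAP targets, the DNA methylation machinery, paternally and maternally expressed imprinted genes, germline genes with methylated promoters, two-cell-like genes, primitive endoderm, trophectoderm, and mesoderm and neural genes, fibroblast genes, glycolysis, cholesterol synthesis, X-linked housekeeping genes, X-linked escape genes, Y-linked genes, and stress genes. Each list was tested with limma's camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Single genes were named by a rule fixed beforehand: a checked set of 24 genes, up to 4 called members of each list with the largest change, and the 6 most raised and 6 most lowered called genes with a mean of at least 5 RPKM in the higher group and no overlap between groups, predicted genes left out. Xist, H19 and Meg3 belonged to the checked set but had no match in the table and were not analysed here. X-linked expression, taken as the X-linked median minus the autosomal median, was compared between XX and XY lines with an exact permutation test within media. The overlap of the t2i and a2i effects, which share the 2i libraries, was set beside 100 simulations of unchanged groups and beside fits in which each comparison had its own 2i libraries. The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Of these, t2i against 2i recovered 88% and 99%, XX against XY in 2i 68% and 96%, sex by medium (2i against t2i) 28% and 89%, 2i against S in the MSM cross 45% and 89%, 2i-S against S 17% and 68%, and the difference between crosses 37% and 92%, with 3 to 11 unchanged genes called.

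The alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, leaving out each library in turn, fits on the 8 libraries of 2 media alone, leaving out sex-linked genes, a term for line numbers shared between media, and an estimated correlation in camera. Added after the data were seen were the subtraction of an estimated fibroblast share (the median, over the listed fibroblast genes abundant in MEFs, of a library's RPKM over the MEF mean) and a fit on genes with under 10% of their serum signal from that share. The remainder was not scaled back up to a full library. Subtracted serum values of the B6 cross are therefore low as a whole, and the values they are compared with read relatively high.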

Results

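The RNA-seq libraries asked how the medium, the sex chromosomes and their combination set the transcriptome of ESC lines, with attention to the DNA methylation machinery and to imprinted genes. Within groups, libraries correlated at 0.987 to 0.996 across genes on the log2 scale, lowest for the MSM-cross 2i XX lines and highest for the t2i XY lines. No pair of libraries was identical.

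XX lines carried more X-linked RNA than XY lines in every medium, as in female ESCs with both X chromosomes active. The X-linked minus autosomal median differed by 0.92 log2 units between XX and XY lines of the B6 cross (431 X-linked and 11561 autosomal genes, n = 8 and 8 lines, exact two-sided permutation p = 0.0015, the smallest value that 1296 arrangements allow). Against the mean of the XY lines, and less the autosomal median, X-linked genes stood 0.87 to 0.98 log2 units higher in the XX lines in 2i, t2i and a2i, and 0.65 to 0.70 higher in the XX lines in serum, whose libraries held fibroblast RNA (8.34% to 11.9% of the MEF level). Subtracting it moved the median XX minus XY difference of X-linked housekeeping genes in serum from 0.59 to 0.77, beside 0.83 in 2i. XX ESCs of the MSM cross stood 0.81 to 1.07 higher, while the MEFs, the XX 2i MEF included, stood at 0.07 to 0.11.

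**Figure D1:**
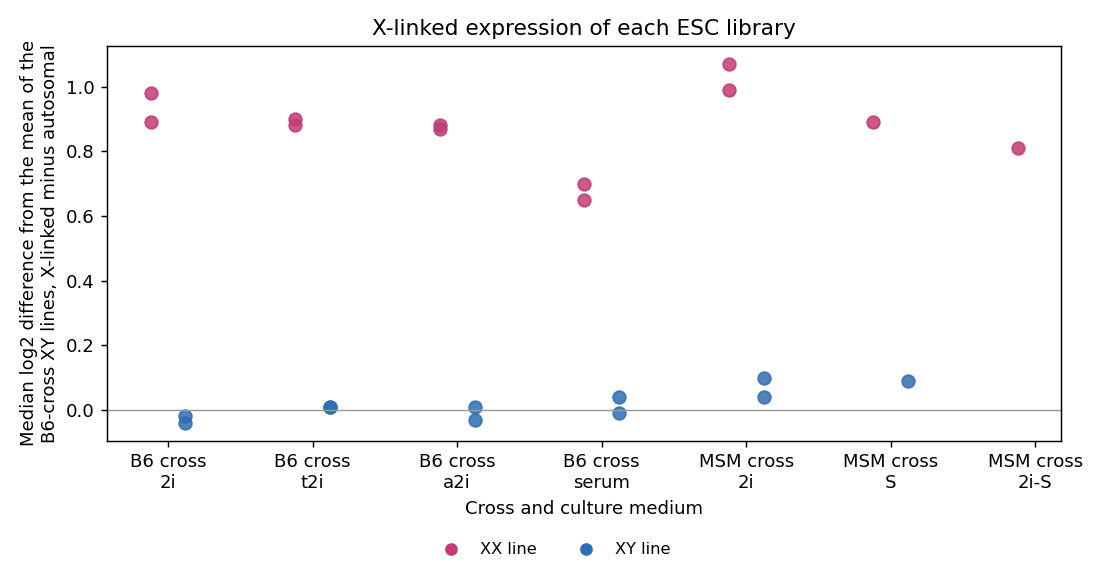
Median log2 difference of X-linked genes from the mean of the B6-cross XY lines, less that of autosomal genes (vertical axis), for each ESC library, by cross and medium (horizontal axis); each point is 1 library, coloured by XX or XY. XX libraries of the B6 cross stand at 0.87 to 0.98 in 2i, t2i and a2i and at 0.65 to 0.70 in serum, where the libraries held fibroblast RNA that was not subtracted here.

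In the B6 cross, 2i lines held less RNA of the de novo DNA methylation enzymes than serum lines (n = 4 and 4 lines). The methyltransferase genes Dnmt3a and Dnmt3b fell by 2.27 (SE 0.19, adjusted p = 7.8e-07) and 1.34 log2 units (SE 0.23, adjusted p = 3.9e-04), and Dnmt3l, which encodes their cofactor, fell by 1.56 (SE 0.14, adjusted p = 1.2e-06). Dnmt1, the maintenance methyltransferase, did not pass the test (0.19, SE 0.11, adjusted p = 0.19). Uhrf1, which brings it to newly copied DNA, rose by 0.51 (SE 0.10, adjusted p = 9.0e-04). Genes downstream of ERK were also lower in 2i: Dusp6, an ERK phosphatase, fell by 2.77 (SE 0.21) and the early response genes Egr1 and Fos fell by 5.65 (SE 0.14) and 6.07 (SE 0.16). Tfcp2l1, a naive pluripotency factor, rose by 1.38 (SE 0.14). Axin2, a Wnt target, rose by 1.72 (SE 0.19). Of the most changed genes, Pglyrp1 rose by 3.85 (SE 0.19) and Bgn, an extracellular matrix gene of fibroblasts, fell by 8.29 (SE 0.18).

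**Figure D2:**
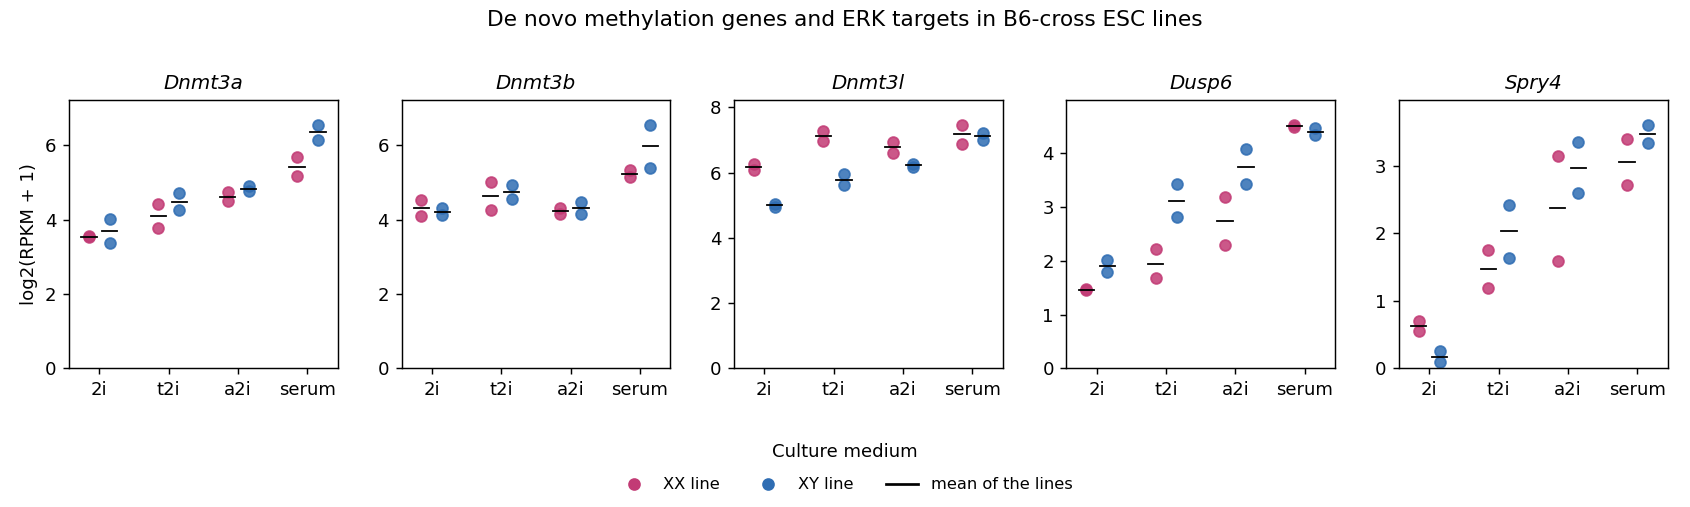
log2(RPKM + 1) of Dnmt3a, Dnmt3b, Dnmt3l, Dusp6 and Spry4 (vertical axis) in B6-cross ESC lines by medium (horizontal axis); points are lines, coloured by XX or XY, and bars are means of the 2 lines. Dnmt3a ran from 9.27 to 15.3 RPKM in 2i and from 34.9 to 93.5 in serum.

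The serum libraries of the B6 cross held fibroblast RNA. All 16 fibroblast genes fell in 2i (list median −5.35, adjusted p = 7.7e-17, adjusted p = 0.023 with an estimated correlation). Serum libraries carried an estimated 8.34% to 11.9% of the MEF level of these genes, and other B6-cross libraries at most 0.0162%. Subtracting this share left Dnmt3a at −2.25 (SE 0.19, adjusted p = 1.9e-06). Among the genes named by the rule it ended the calls of Igf2, Dlk1, Acta2, Hmgcs1, Hspa1b and Flna (−0.64 before, 0.10 after, SE 0.14, adjusted p = 0.56), left S100a4 untested and turned Msn from −0.49 to 0.75 (SE 0.20, adjusted p = 0.0074). The fibroblast list, of which 9 genes were then tested, then stood at a median of −2.81.

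Among 20 ERK pathway targets, 17 fell and 1 rose in 2i (median −1.61, adjusted p = 3.1e-06, adjusted p = 0.36 with an estimated correlation), with Spry4 at −2.86 (SE 0.31) and Etv4 at −1.48 (SE 0.26); adjusted over the list alone, 17 fell and 2 rose. With the fibroblast RNA of the serum libraries (8.34% to 11.9%) subtracted, the median was −1.21. Of 13 formative and primed epiblast genes, 12 fell (median −1.22, adjusted p = 3.3e-04, adjusted p = 0.3 with an estimated correlation; −0.68 after subtraction), including Fgf5 (−1.51, SE 0.10) and Pou3f1 (−1.42, SE 0.12). Of 12 YAP targets, 10 fell (median −1.18, adjusted p = 1.4e-04, adjusted p = 0.15 with an estimated correlation; −0.61 after subtraction), including Cyr61 (−3.37, SE 0.15) and Ctgf (−3.37, SE 0.14), which fibroblasts also express. Of 16 naive pluripotency genes, 8 rose and 3 fell (adjusted p = 0.019, adjusted p = 0.36 with an estimated correlation). Of the 12 primitive endoderm genes, 9 fell (adjusted p = 4.6e-04, adjusted p = 0.36 with an estimated correlation), with Dab2 at −3.74 (SE 0.26) beside the same fibroblast RNA. After subtraction 8 of these genes fell and 1 rose (median −1.43 before and −1.18 after).

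Of 15 genes of the DNA methylation machinery, 7 fell and 2 rose (adjusted over the list alone, 8 fell and 2 rose), with a list adjusted p of 0.42. Of 13 maternally expressed imprinted genes, 9 fell and 1 rose (median −0.79, adjusted p = 0.018, adjusted p = 0.36 with an estimated correlation), among them Phlda2 (−3.22, SE 0.21) and Cdkn1c (−2.66, SE 0.15), both of the imprinted cluster on distal chromosome 7. Of 22 paternally expressed imprinted genes, 12 fell and 3 rose (list adjusted p = 0.12), with Peg10 at −2.66 (SE 0.21) and Plagl1 at 2.88 (SE 0.20). Of 18 germline genes with methylated promoters, 9 rose and 5 fell (list adjusted p = 0.12). Among them Dazl rose by 1.98 (SE 0.17) and Fkbp6 by 2.49 (SE 0.15), while Mael fell by 2.16 (SE 0.21). These groups, too, were compared with serum libraries that held the fibroblast share of 8.34% to 11.9%. After its subtraction 8 paternally expressed genes fell and 6 rose, and of the maternally expressed genes 7 fell and 2 rose (median −0.42).

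The other lists did not pass the test in 2i against serum. Of 10 core pluripotency genes, 5 fell and 1 rose (adjusted p = 0.27), among them Lin28a (−1.98, SE 0.18) and Utf1 (−1.77, SE 0.10). Wnt targets split into 4 higher and 4 lower of 10 (adjusted p = 0.35), but into 5 higher and 1 lower after quantile normalization (median 0.40) and 5 higher and 2 lower of 9 after subtraction (median 0.32). Trophectoderm genes split into 2 higher and 6 lower of 10 (adjusted p = 0.28), and mesoderm and neural genes into 1 higher and 3 lower of 5 (adjusted p = 0.43; 1 and 1 after quantile normalization). All 3 two-cell-like genes fell (adjusted p = 0.062). Of 14 glycolysis genes 6 fell and 1 rose (adjusted p = 0.49; 4 and 1 after subtraction). Of 17 cholesterol synthesis genes 8 fell (adjusted p = 0.12), although after the fibroblast share was subtracted 4 rose and 3 fell. Of 27 X-linked housekeeping genes 4 rose and 6 fell (median 0.04, mean −0.12 and a test pointing up, adjusted p = 0.48; adjusted over the list alone, 3 rose and 6 fell). This split depended on the processing. After subtraction 11 rose and 2 fell (median 0.17, beside 0.08 for all genes), and after quantile normalization 2 rose and 7 fell. Of 4 X-linked escape genes 1 fell (median −0.02, mean −0.13, with the test pointing up, adjusted p = 0.97). Of 3 Y-linked genes 2 fell (adjusted p = 0.39; 1 after quantile normalization). These values average both sexes, and the serum XX lines held Y-linked RNA, which XX cells cannot make. Eif2s3y read 1.37 and 1.64 RPKM in them and is listed at 0 in the 2i XX lines. Of 9 stress genes 3 rose and 2 fell (median 0.05, mean −0.05, adjusted p = 0.35).

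Of 13150 genes tested in 2i against serum, 2215 were higher and 4042 lower in 2i. The split depends on the scaling. After quantile normalization, which moved the median of all genes by 0.17, 3877 were higher and 2764 lower. With the fibroblast share subtracted, 3577 were higher and 2597 lower. Subtraction without scaling of the remainder moved the median of all genes from −0.09 to 0.08, so this split also depends on the method. Of 7847 genes with under 10% of their serum signal from that share, 1624 were higher and 1859 lower.

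Lowering the MEK inhibitor changed a smaller set of genes, and the cofactor of the de novo enzymes was among them. Dnmt3l was higher in t2i than in 2i by 0.87 log2 units (SE 0.14, adjusted p = 0.0024, n = 4 and 4 lines) and Dnmt3a by 0.67 (SE 0.19, adjusted p = 0.048). Dnmt3b did not pass the test (0.43, SE 0.23, adjusted p = 0.3). Dnmt3a kept its call only without t2i XX line 3 (0.51 to 0.84 over all fits) or without 2i XY line 2. The germ cell gene Dazl fell by 1.44 (SE 0.17), and Lin28a, an RNA-binding protein of early pluripotent cells, rose by 1.15 (SE 0.18). Phlda2 rose by 2.11 (SE 0.21), Cdkn1c by 1.46 (SE 0.15) and Slc22a18 by 1.13 (SE 0.14), all from the imprinted cluster on distal chromosome 7. These are means of the XX and XY differences, and each of these genes rose more in XX lines. Cdkn1c went from 0.912 and 0.479 RPKM in 2i to 7.97 and 8.63 in t2i in XX lines. In XY lines it went from 3.18 and 4.34 to 4.80 and 6.22. The cell cycle inhibitor Cdkn2a fell by 1.35 (SE 0.12) and Tnni1 by 1.43 (SE 0.16).

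Of 20 ERK pathway targets, 3 rose from 2i to t2i and none fell (list adjusted p = 0.37; adjusted over the list alone, 4 rose and 1 fell): Ccnd1 (0.66, SE 0.13), Dusp6 (0.85, SE 0.21) and Spry4 (1.35, SE 0.31). Left-out libraries ended the last pair of calls: Dusp6 stayed called only without t2i XX line 3 or t2i XY line 6 (0.70 at the lowest), and Spry4 only without t2i XX line 3, 2i XY line 2 or t2i XY line 6 (1.16 to 1.55). Of 13 maternally expressed imprinted genes, 4 rose (adjusted over the list alone, 5 rose; median 0.20, adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation). Of 10 core pluripotency genes 3 rose (adjusted p = 0.014, adjusted p = 0.21 with an estimated correlation), with Utf1 at 0.81 (SE 0.10) and Tdgf1 at 0.81 (SE 0.14). Of 12 YAP targets 3 fell (adjusted over the list alone, 5 fell; adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation), with Cyr61 at −1.21 (SE 0.15). Of 18 germline genes 5 fell (adjusted over the list alone, 7 fell; list adjusted p = 0.051). Of 17 cholesterol synthesis genes 1 rose (adjusted p = 0.029, adjusted p = 0.96 with an estimated correlation). Of 15 DNA methylation genes 2 rose (list adjusted p = 0.37), and none of 16 naive genes changed (list adjusted p = 0.93). Of 3 Y-linked genes 2 fell (adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation). Against the mean of the other XY lines, Ddx3y, Eif2s3y and Uty stood at 31.8%, 19.3% and 31.4% in t2i XY line 2 and at 53.8%, 42.0% and 75.5% in t2i XY line 6.

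In t2i against 2i, 551 genes were higher and 511 lower, 1062 in all (483 and 517 after quantile normalization). Leaving out any library but t2i XX line 3 lowered the count to between 569 (without t2i XY line 2) and 669. A fit of the 8 libraries of t2i and 2i alone called 415 genes, and of the genes given here Dnmt3a, Dusp6, Ccnd1 and Cdkn1c lost their calls in it.

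With a Src inhibitor in place of the MEK inhibitor, several ERK targets, Dnmt3a and Dnmt3l were higher. From 2i to a2i, Dusp6 rose by 1.57 log2 units (SE 0.21, adjusted p = 5.6e-04, n = 4 and 4 lines), Spry4 by 2.27 (SE 0.31), the phosphatase gene Dusp4 by 1.17 (SE 0.24) and Egr1 by 1.08 (SE 0.14). Dnmt3a rose by 1.11 (SE 0.19, adjusted p = 0.0022) and Dnmt3l by 0.91 (SE 0.14, adjusted p = 9.4e-04). Dnmt3b stood at 0.01 (SE 0.23, adjusted p = 0.99). The secreted factor gene Bmp4 rose by 2.53 (SE 0.23) and the tight junction gene Cldn6 by 2.26 (SE 0.17), and Tnni1 fell by 1.99 (SE 0.16). Dazl fell by 1.33 (SE 0.17) and Plagl1 by 1.61 (SE 0.20). Phlda2 rose by 2.35 (SE 0.21), Slc22a18 by 1.28 (SE 0.14) and Cdkn1c by 1.20 (SE 0.15).

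ERK pathway targets were higher in a2i: of 20, 9 rose and none fell (median 0.47, adjusted p = 0.0059, adjusted p = 0.99 with an estimated correlation; adjusted over the list alone, 10 rose and 1 fell). Of 13 maternally expressed imprinted genes 7 rose and 1 fell (median 0.47, adjusted p = 0.0059, adjusted p = 0.62 with an estimated correlation; adjusted over the list alone, 8 rose and 1 fell). Of 22 paternally expressed genes 3 rose and 3 fell (adjusted over the list alone, 5 and 5). Of 14 glycolysis genes 1 rose (median 0.27, adjusted p = 0.012, adjusted p = 0.99 with an estimated correlation). Of 10 core pluripotency genes 3 rose (adjusted p = 0.029, adjusted p = 0.42 with an estimated correlation). Of 15 DNA methylation genes 3 rose (list adjusted p = 0.63). The third, Tet1, which oxidizes methylated cytosine, stood at 0.57 (SE 0.14, adjusted p = 0.016) and lost its call without 2i XX line 4 or without a2i XY line 1 (0.41 to 0.73). Germline genes moved both ways, 4 rising and 7 falling of 18 (median 0.02, mean −0.13, list adjusted p = 0.57), with Mael at 1.07 (SE 0.21) and Hormad1 at −1.06 (SE 0.16). In all, 1044 genes were higher in a2i and 769 lower (837 and 880 after quantile normalization), and a fit of the 8 libraries alone called 706, without Tet1, Mael, Slc22a18 and Cdkn1c.

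The t2i and a2i effects overlapped: 752 genes were called in both in the same direction (403 higher and 349 lower) and 0 in opposite directions. Independent lists would share 43.7 higher and 29.9 lower genes. The effects correlated at 0.76 with a covariance of 0.078, where simulated unchanged groups against the same 2i libraries gave 0.50 and 0.013. With each comparison given its own 2i libraries, 230 to 250 genes were shared, at correlations of 0.51 to 0.63 and covariances of 0.061 to 0.070.

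Between a2i and t2i directly, Egr1 was higher in a2i by 1.11 log2 units (SE 0.14, adjusted p = 0.0063, n = 4 and 4 lines) and Dmrt1, a germline transcription factor gene, by 1.06 (SE 0.15, adjusted p = 0.0083). The intermediate filament gene Vim fell by 1.18 (SE 0.18, adjusted p = 0.013). This call ended without t2i XX line 1, t2i XY line 2 or a2i XY line 3 (−1.36 at the lowest). Dnmt3a (0.43, SE 0.19, adjusted p = 0.32), Dnmt3l (0.04, SE 0.14, adjusted p = 0.94) and Dusp6 (0.72, SE 0.21, adjusted p = 0.13) did not pass the test. Of 20 ERK pathway targets 2 rose (median 0.16, adjusted p = 0.004, adjusted p = 0.87 with an estimated correlation; adjusted over the list alone, 7 rose and 1 fell). Of 3 Y-linked genes 1 rose (adjusted p = 0.014, adjusted p = 0.87 with an estimated correlation; adjusted over the list alone, 2 rose). In all, 93 genes were higher and 39 lower (132, with 1878 at an unadjusted p under 0.05 in limma). Without single libraries the count fell to 22 (t2i XX line 1), 21 (t2i XY line 2), 36 (t2i XY line 6), 44 (a2i XY line 1) and 17 (a2i XY line 3), and a fit of the 8 libraries of both media alone called 1, in which Egr1, Dmrt1 and Vim all lost their calls.

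Lines in t2i and a2i also held less RNA of the de novo methylation genes than serum lines. Dnmt3a stood at −1.60 (SE 0.19) in t2i and −1.16 (SE 0.19) in a2i, Dnmt3b at −0.92 (SE 0.23) and −1.33 (SE 0.23), and Dnmt3l at −0.69 (SE 0.14) and −0.65 (SE 0.14), each with n = 4 and 4 lines. Dusp6 stood at −1.92 (SE 0.21) in t2i and −1.21 (SE 0.21) in a2i, and Spry4 at −1.51 (SE 0.31) in t2i. In a2i it did not pass the test (−0.59, SE 0.31, adjusted p = 0.16). Tfcp2l1 rose by 1.39 (SE 0.14) in t2i and by 1.40 (SE 0.14) in a2i.

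ERK pathway targets fell in both media against serum, 17 of 20 in t2i (median −1.37, adjusted p = 1.3e-06) and 15 in a2i (adjusted p = 9.2e-06), each with adjusted p = 0.36 with an estimated correlation. Beside the fibroblast RNA of the serum libraries (8.34% to 11.9%), the medians after subtraction were −0.84, with 14 called lower, and −0.48, with 9. Formative genes fell in 13 of 13 and 12 of 13 cases (adjusted p = 1.8e-05 in t2i and 2.9e-05 in a2i; adjusted p = 0.17 and adjusted p = 0.18 with an estimated correlation). After subtraction 12 fell and 1 rose in t2i (median −0.79) and 9 fell and 1 rose in a2i (median −0.72), and after quantile normalization 9 fell in t2i (median −0.88) and 8 in a2i (median −0.61). YAP targets, which fibroblasts also express, fell in 11 of 12 cases in t2i (median −1.60, adjusted p = 1.3e-06, adjusted p = 0.051 with an estimated correlation) and 10 of 12 in a2i (median −1.51, adjusted p = 1.0e-06, adjusted p = 0.048 with an estimated correlation). After subtraction 8 fell in t2i (median −0.85) and 7 in a2i. All 16 fibroblast genes fell in both (adjusted p = 0.017 in t2i and adjusted p = 0.011 in a2i with an estimated correlation). Of 22 paternally expressed imprinted genes, 13 fell and 1 rose in a2i (median −0.47, adjusted p = 0.012, adjusted p = 0.25 with an estimated correlation). After subtraction 7 fell and 3 rose (median −0.28). In all, 2010 genes were higher and 3747 lower in t2i, and 1636 higher and 3282 lower in a2i. After quantile normalization these splits were 3755 to 2517 and 3345 to 2234 (medians of all genes moved by 0.16 and 0.14). With the share subtracted and the remainder not scaled they were 3327 to 2266 and 3051 to 1848. The medians of all genes moved from −0.07 in t2i and −0.06 in a2i to 0.09 in both.

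XX and XY lines in 2i differed in pluripotency, imprinted and X-linked genes. In XX lines Dnmt3l was higher by 1.18 log2 units (SE 0.19, adjusted p = 7.9e-04, n = 2 and 2 lines). So were the naive pluripotency regulators Prdm14 and Nanog by 1.16 (SE 0.14, adjusted p = 9.7e-05) and 1.10 (SE 0.13, adjusted p = 6.3e-05). Dppa3, which protects methylation in the early embryo, was higher by 1.57 (SE 0.30, adjusted p = 0.0021). Dnmt3a (−0.15, SE 0.27, adjusted p = 0.75) and Dnmt3b (0.09, SE 0.33, adjusted p = 0.89) did not pass the test. The X-linked genes Klhl13 and Dusp9, a MAP kinase phosphatase gene, were higher by 3.38 (SE 0.20) and 2.97 (SE 0.13). Of 10 trophectoderm genes 3 were higher and 5 lower (median −0.68, adjusted p = 0.55), and of 9 stress genes 1 was higher and 4 lower (median −0.35, adjusted p = 0.084); neither list passed the test.

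Of the maternally expressed genes of distal chromosome 7, 4 were lower in XX lines. Slc22a18 stood at 0.538 and 0.370 RPKM in XX lines and 8.04 and 6.57 in XY lines (−2.51, SE 0.20, adjusted p = 4.0e-06), Phlda2 at −1.73 (SE 0.30), Ascl2 at −1.58 (SE 0.22) and Cdkn1c at −1.49 (SE 0.22). The other list members tested in this region, named after their values were seen, did not pass the test: Osbpl5 (−0.39, SE 0.18, adjusted p = 0.13), Tnfrsf23 (0.10, SE 0.19), Cd81 (0.06, SE 0.12) and Tssc4 (0.12, SE 0.12). Of 13 maternally expressed imprinted genes 8 fell (median −0.59, adjusted p = 9.4e-04, adjusted p = 0.18 with an estimated correlation). Of 22 paternally expressed genes 8 rose (median 0.39, adjusted p = 0.0021, adjusted p = 0.15 with an estimated correlation; adjusted over the list alone, 9 rose and 1 fell), Peg12 by 2.61 (SE 0.19) and Ndn by 2.01 (SE 0.16) among them. Of 16 naive genes 6 rose (adjusted p = 0.0097, adjusted p = 0.38 with an estimated correlation). Of 27 X-linked housekeeping genes 20 rose (median 0.83, adjusted p = 1.2e-14, adjusted p = 0.0013 with an estimated correlation). So did 3 of 4 escape genes (adjusted p = 0.0012, adjusted p = 0.18 with an estimated correlation). All 3 Y-linked genes fell (adjusted p = 2.8e-05, adjusted p = 0.15 with an estimated correlation), Ddx3y and Eif2s3y being listed at 0 in the XX lines.

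**Figure D3:**
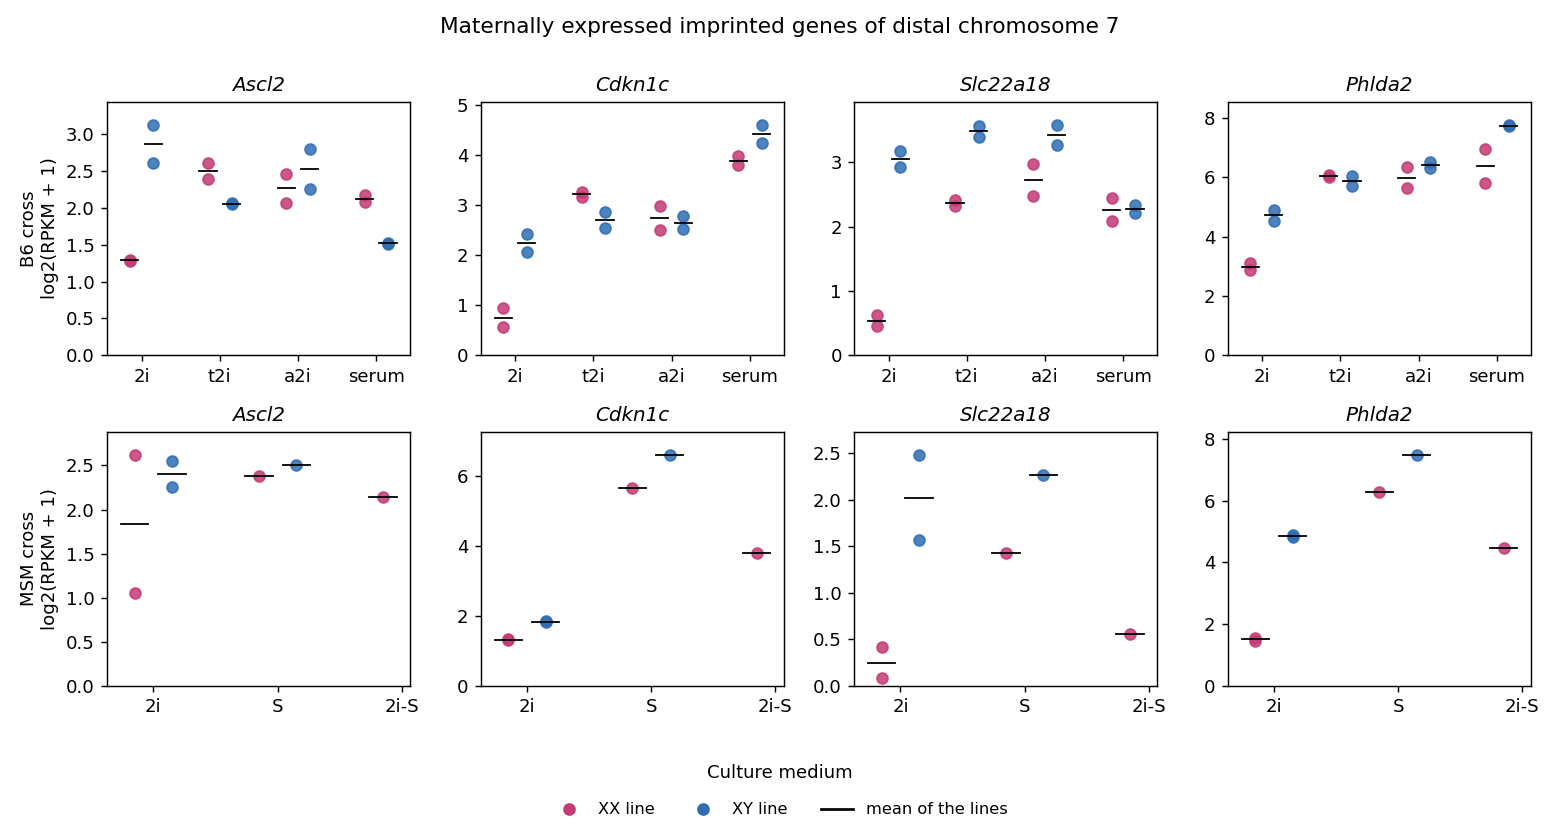
log2(RPKM + 1) of Ascl2, Cdkn1c, Slc22a18 and Phlda2 (vertical axis) by medium (horizontal axis) in B6-cross lines (top) and MSM-cross lines (bottom); points are lines, coloured by XX or XY, and bars are means of the lines of a group. Slc22a18 stood at 0.538 and 0.370 RPKM in the B6-cross 2i XX lines and at 8.04 and 6.57 in the XY lines.

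In all, 1564 genes were higher and 1741 lower in XX lines in 2i (331 and 10 of 474 X-linked genes, 1233 and 1728 autosomal genes). Without 2i XY line 2 the total of 3305 was 1965, and without 2i XX line 4 it was 2094.

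In t2i, XX lines again held more Dnmt3l (1.35, SE 0.19, adjusted p = 4.5e-04, n = 2 and 2 lines) and Nanog (0.86, SE 0.13). They held less of the mesoderm gene T (−2.13, SE 0.38). Of 14 glycolysis genes 9 rose (median 0.66, adjusted p = 1.8e-06, adjusted p = 0.4 with an estimated correlation), among them X-linked Pgk1 (1.92, SE 0.20) and the autosomal Ldha (1.61, SE 0.20) and Slc2a1 (1.44, SE 0.24). Of 18 germline genes 7 rose (median 0.61, adjusted p = 0.0034, adjusted p = 0.52 with an estimated correlation; adjusted over the list alone, 10 rose and 1 fell), with Hormad1 at 1.88 (SE 0.22) and Tuba3a at 2.16 (SE 0.34). Of 22 paternally expressed imprinted genes 6 rose and 3 fell (adjusted p = 0.042, adjusted p = 0.4 with an estimated correlation). Of 12 YAP targets 5 rose (adjusted p = 0.033, adjusted p = 0.4 with an estimated correlation). Of 10 Wnt targets 3 fell (adjusted p = 0.023, adjusted p = 0.61 with an estimated correlation). Of 13 maternally expressed imprinted genes 3 fell (list adjusted p = 0.49), with Slc22a18 at −1.12 (SE 0.20). In all, 1451 genes were higher and 1037 lower (302 and 5 of the X-linked genes). The total of 2488 was 1260 without t2i XY line 2, 1603 without t2i XX line 3 and 1464 without t2i XY line 6.

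In a2i, Prdm14 (1.21, SE 0.14), Nanog (1.08, SE 0.13) and Dazl (1.44, SE 0.24) were higher in XX lines (n = 2 and 2 lines). Dnmt3l did not pass the test (0.55, SE 0.19, adjusted p = 0.051). Of 18 germline genes 8 rose (median 0.65, adjusted p = 4.7e-04, adjusted p = 0.61 with an estimated correlation), including Hormad1 (2.45, SE 0.22) and Tuba3a (2.68, SE 0.34). Of 14 glycolysis genes 8 rose (median 0.66, adjusted p = 1.0e-04, adjusted p = 0.61 with an estimated correlation), including Slc2a3 (1.75, SE 0.14). In all, 2214 genes were higher and 1512 lower (1668 and 1719 after quantile normalization). The total of 3726 was 2153 without a2i XY line 3.

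In serum, XX lines held more of the naive regulators Prdm14 (1.07, SE 0.14), Nanog (0.82, SE 0.13), Klf2 (1.21, SE 0.20) and Tbx3 (2.48, SE 0.27; n = 2 and 2 lines). Dnmt3a (−0.93, SE 0.27, adjusted p = 0.058) and Dnmt3l (0.07, SE 0.19, adjusted p = 0.89) did not pass the test. Of 16 naive genes 9 rose (median 0.66, adjusted p = 2.7e-07, adjusted p = 0.1 with an estimated correlation; adjusted over the list alone, 10 rose and 2 fell). Of 18 germline genes 9 rose (median 0.81, adjusted p = 4.6e-09, adjusted p = 0.11 with an estimated correlation), Fkbp6 by 2.02 (SE 0.22) among them. Of 3 two-cell-like genes 2 rose (adjusted p = 7.5e-04, adjusted p = 0.12 with an estimated correlation). Of 17 cholesterol synthesis genes 2 fell (adjusted p = 1.4e-04, adjusted p = 0.3 with an estimated correlation). Of 16 fibroblast genes 1 fell (adjusted p = 0.012, adjusted p = 0.34 with an estimated correlation). The estimated fibroblast share was 8.34% and 11.4% in the XX lines and 11.2% and 11.9% in the XY lines. In all, 724 genes were higher and 234 lower (742 and 452 after quantile normalization). The total of 958 was 419 without serum XY line 16, 426 without serum XY line 10 and 462 without serum XX line 17.

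The size of the sex difference depended on the medium for some genes. Khdc3, an oocyte gene, had a lower XX minus XY difference in 2i than in t2i (−4.58 log2 units, SE 0.34, adjusted p = 9.4e-05, n = 2 lines in each of 4 groups), than in a2i (−3.27, SE 0.34) and than in serum (−3.59, SE 0.34). The distal chromosome 7 gene Ascl2 had a lower difference in 2i than in t2i (−2.03, SE 0.31, adjusted p = 0.0082), and Slc22a18 than in a2i (−1.80, SE 0.28, adjusted p = 0.006) and in serum (−2.50, SE 0.28, adjusted p = 3.3e-04). Dppa3 had a difference higher in 2i than in a2i by 2.48 (SE 0.42) and than in serum by 2.46 (SE 0.42). Dnmt3a (0.23, SE 0.38, adjusted p = 0.85), Dnmt3b (0.20, SE 0.46, adjusted p = 0.9) and Dnmt3l (−0.16, SE 0.27, adjusted p = 0.85) did not pass the test between 2i and t2i.

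Between 2i and t2i, 3 of 13 maternally expressed imprinted genes had a lower difference in 2i (median −0.23, adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation; adjusted over the list alone, 5). So had 1 of 18 germline genes (median −0.63, adjusted p = 4.1e-04, adjusted p = 0.55 with an estimated correlation; adjusted over the list alone, 6) and 1 of 14 glycolysis genes (median −0.58, adjusted p = 5.2e-05, adjusted p = 0.55 with an estimated correlation; adjusted over the list alone, 7). After quantile normalization none of the germline or glycolysis genes was called. Between 2i and a2i, 3 maternally expressed genes (median −0.59, adjusted p = 0.0014, adjusted p = 0.43 with an estimated correlation) and 4 germline genes (median −0.94, adjusted p = 1.3e-04, adjusted p = 0.58 with an estimated correlation; 2 of each after quantile normalization) had a lower difference in 2i. Between 2i and serum, 6 germline genes (median −1.20, adjusted p = 1.5e-05, adjusted p = 0.33 with an estimated correlation) and 4 stress genes (median −0.85, adjusted p = 0.0036, adjusted p = 0.33 with an estimated correlation) did, with 1 stress gene higher, beside the fibroblast share of the serum libraries (8.34% to 11.9%). The germline genes in this group include Mael (−2.10, SE 0.43), Taf7l (−1.73, SE 0.25) and Fkbp6 (−1.67, SE 0.31).

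The difference was called for 166 genes between 2i and t2i (49 higher and 117 lower), 648 between 2i and a2i (213 and 435; 200 and 245 after quantile normalization) and 1074 between 2i and serum (414 and 660). Without single libraries the 166 ran from 46 (without t2i XY line 2) to 87, except without t2i XX line 1 (123). The 648 fell to between 161 (without 2i XY line 2) and 404 without any library but a2i XX lines 4 and 18. The 1074 fell as far as 582 (without 2i XY line 2), staying within 1.5 times only without serum XX line 46 or 2i XY line 6.

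In the MSM cross, 2i lines also held less RNA of the de novo enzymes than serum lines (n = 4 and 2 lines). Dnmt3b fell by 3.52 log2 units (SE 0.22, adjusted p = 3.4e-04) and Dnmt3a by 2.02 (SE 0.22, adjusted p = 0.0019). Dnmt3l fell by 1.76 (SE 0.48, adjusted p = 0.041), a call kept only without 2i XX line 15 or 2i XX line 2 (−2.19 to −1.33). Dusp6 fell by 2.61 (SE 0.28) and Egr1 by 4.73 (SE 0.45). Prdm14 rose by 1.67 (SE 0.23), Tfcp2l1 by 2.23 (SE 0.23) and Zfp57, which guards methylation at imprinted loci, by 1.11 (SE 0.13). Among imprinted genes Cdkn1c fell by 4.55 (SE 0.41), Phlda2 by 3.71 (SE 0.41) and Grb10 by 1.88 (SE 0.15).

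Of 20 ERK pathway targets 14 fell and 1 rose (median −1.10, adjusted p = 3.5e-07, adjusted p = 0.45 with an estimated correlation; adjusted over the list alone, 17 fell and 1 rose). The estimated fibroblast share was 0.442% and 1.32% in the S lines, 0.815% in 2i XY line 20 and at most 0.028% in the other 2i lines, and the ERK median was −1.08 after its subtraction. Of 16 fibroblast genes 8 fell (median −1.30, adjusted p = 2.8e-05, adjusted p = 0.5 with an estimated correlation; adjusted over the list alone, 11 fell), with a median of 0.00 after subtraction. Of 16 naive genes 6 rose and 1 fell (adjusted p = 0.0013, adjusted p = 0.5 with an estimated correlation). Of 13 formative genes 5 fell (adjusted p = 0.0026, adjusted p = 0.45 with an estimated correlation). Of 13 maternally expressed imprinted genes 4 fell and 1 rose (adjusted p = 0.0061, adjusted p = 0.46 with an estimated correlation). In all, 1124 genes were higher and 1166 lower. The total of 2290 was 662 without S XY line 12, 949 without S XX line 8 and 1281 without 2i XY line 20.

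The 2i line moved to serum stood between its media for the de novo enzymes. It had also been passaged further than the 2i and S lines, so medium history and time in culture cannot be told apart. Dnmt3b read 47.0 RPKM in the 2i-S line, 9.86 to 19.8 in 2i lines and 150.1 and 172 in S lines. Dnmt3a read 54.1, 27.0 to 33.4, and 96.9 and 161. Against 2i (n = 1 and 4, the parent line 15 among the 4, the spread of 2i-S cultures not measured), Dnmt3b stood at 1.95 (SE 0.31, adjusted p = 0.041), kept only without 2i XY line 23 (1.82 to 2.02). The same held for Dusp6 (2.45, SE 0.39, adjusted p = 0.041, 2.15 to 2.53). Dnmt3a (0.86, SE 0.30, adjusted p = 0.21) did not pass the test. Of 20 ERK pathway targets 3 rose (adjusted p = 9.9e-07, adjusted p = 0.4 with an estimated correlation; adjusted over the list alone, 10 rose and 1 fell). Of 21 paternally expressed imprinted genes 3 rose (adjusted p = 0.012, adjusted p = 0.4 with an estimated correlation). Of 16 fibroblast genes 4 rose (median 1.91, adjusted p = 3.2e-10, adjusted p = 0.4 with an estimated correlation). The fibroblast share of the 2i-S library was 1.37%. The 109 higher and 55 lower genes (164) became 0 without 2i XX line 2, 11 without 2i XX line 15, 72 without 2i XY line 20 and 106 without 2i XY line 23.

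Against the lines derived in serum (n = 1 and 2), 0 genes were higher and 1 lower in the 2i-S line by limma, with 561 at an unadjusted p under 0.05. The called gene, the predicted X-linked gene Gm17604, lies outside the naming rule and was chosen after its values were seen. It read 69.8 and 70.1 RPKM in the S lines and is listed at 0 in the 2i-S library. Leaving out either S line removed the gene by the filter, which asks for at least 1 RPKM in at least 2 libraries. Its stability could therefore not be tested in this way. Dnmt3b (−1.56, SE 0.33), Dnmt3a (−1.16, SE 0.33) and Dusp6 (−0.16, SE 0.42) each had an adjusted p of 1. Lists shifted without a called member: naive genes up (median 0.51, adjusted p = 2.9e-04, adjusted p = 0.5 with an estimated correlation), formative genes down (median −0.50, adjusted p = 2.9e-04, adjusted p = 0.35 with an estimated correlation) and fibroblast genes up (median 0.71, adjusted p = 0.0014, adjusted p = 0.5 with an estimated correlation). With 1 library on a side, a 2-fold change was recovered in 17% of simulated genes, so the near absence of calls does not show that the cultures were alike.

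In the 1 library of fibroblasts derived from 2i line 15, the imprinted genes Igf2r, Grb10 and Igf2 read lower, and Mest higher, than in the MEF libraries. Its labels also give more passages than those of the MEFs, so origin and passage cannot be told apart. The spread among 2i MEFs was not measured, so the SE and p-values take it from the other groups of the fit and say nothing of other 2i MEF cultures. Igf2r, whose product clears the growth factor IGF2, read 1.71 RPKM in the 2i MEF library and 61.2 and 57.8 in the MEF libraries (−4.48, SE 0.29, adjusted p = 0.0016, n = 1 and 2). The growth regulator Grb10 read 4.38 against 225 and 172 (−5.20, SE 0.22, adjusted p = 1.1e-04), and Igf2 14.4 against 792 and 309 (−5.01, SE 0.51, adjusted p = 0.019). Mest, a paternally expressed gene, read 91.5 against 12.8 and 7.70 (3.08, SE 0.34, adjusted p = 0.021). Its call ended without MEF line 4 (2.74 to 3.41).

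In the 2i MEF, 2 of 13 maternally expressed imprinted genes fell (median −0.42, adjusted p = 3.1e-07, adjusted p = 0.21 with an estimated correlation; adjusted over the list alone, 5 fell). Of 21 paternally expressed ones 1 rose and 1 fell (median 0.42, adjusted p = 5.7e-04, adjusted p = 0.21 with an estimated correlation; adjusted over the list alone, 3 rose and 2 fell). No ERK pathway target of 20 passed the test over all genes (median −0.94, adjusted p = 3.1e-07, adjusted p = 0.32 with an estimated correlation; adjusted over the list alone, 5 fell). In all, 17 genes were higher and 44 lower (35 and 39 after quantile normalization). The total of 61 was 7 without MEF line 4 and 109 without MEF line 2.

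**Figure D4:**
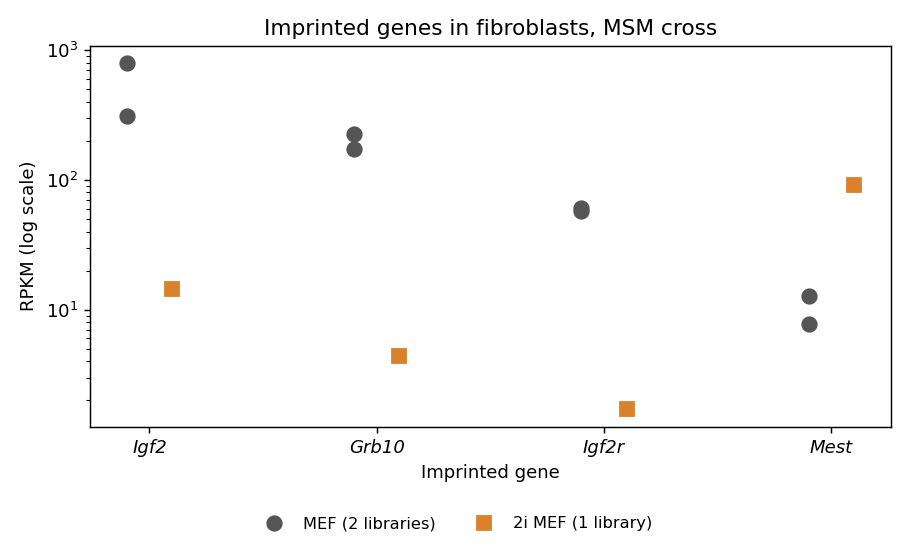
RPKM on a log axis (vertical) of Igf2, Grb10, Igf2r and Mest (horizontal axis) in 2 MEF libraries and 1 2i MEF library of the MSM cross; each point is 1 library. Grb10 stood at 225 and 172 RPKM in MEFs and at 4.38 in the 2i MEF.

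The 2i against serum effect differed between the sets of libraries of the 2 crosses for part of the genes. All Y-linked and mitochondrial loci are listed at 0 in the MSM-cross set, and whether that set was processed apart from the B6-cross set is not given in the sources used here, so cross and processing cannot be told apart. Dnmt3b fell further in the MSM cross than in the B6 cross (−2.17 log2 units, SE 0.40, adjusted p = 0.0042, n = 6 and 8 libraries). The responses of Dnmt3a (0.25, SE 0.35, adjusted p = 0.69), Dnmt3l (−0.20, SE 0.56, adjusted p = 0.85) and Dusp6 (0.16, SE 0.32, adjusted p = 0.78) did not differ by the test. Cdkn1c also fell further in the MSM cross (−1.89, SE 0.32). The receptor gene Axl (4.46, SE 0.36) and the YAP target Ctgf (3.35, SE 0.57) fell less in the MSM cross. Fibroblasts express both genes, and the fibroblast share was 8.34% to 11.9% in the serum lines of the B6 cross and 0.442% and 1.32% in those of the MSM cross.

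Of 16 fibroblast genes 15 had a higher 2i against serum value in the MSM cross (median 3.74, adjusted p = 1.7e-15, adjusted p = 0.15 with an estimated correlation), and 2 of 10 tested after subtraction. The same held for 8 of 12 YAP targets (median 1.39, adjusted p = 2.2e-05, adjusted p = 0.15 with an estimated correlation), while 3 of 12 were called after subtraction (median 0.76). It also held for 6 of 17 cholesterol synthesis genes (median 0.48, adjusted p = 1.0e-03, adjusted p = 0.71 with an estimated correlation), of which 0 stayed called after subtraction (median 0.06). In all, 1263 genes were higher and 281 lower (1544). Quantile normalization, which moved the median of all genes by −0.19, gave 693 and 505, and subtraction gave 455 and 379. Without S XY line 12 the total was 699. Of 12689 genes tested in both crosses, 641 were higher in 2i in both, 843 lower in both and 76 called in opposite directions, where independent lists would share 185 and 343. Among 7420 genes with under 10% of their B6-cross serum signal from fibroblasts, these were 451, 497 and 26 (146 and 164 for independent lists).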

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

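Of the tests in this part, those of the fibroblast transcripts and of the Y-linked RNA were chosen after the result was seen. That of the ERK pathway targets rests on the fibroblast subtraction, which was added after the data were seen. Those of the distal chromosome 7 genes were written before they were run, for a pattern already seen in the B6 cross. The others were written beforehand.

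The B6-cross serum libraries held fibroblast genes at 8.34% to 11.9% of their MEF level, and RNA from fibroblasts in the culture is a candidate explanation. Of 57 genes with a MEF mean of at least 100 RPKM and under 1 RPKM in 2i ESCs, 84.2% stood within 3-fold of a common fraction (median 10.9%), which is what admixed fibroblasts would give. Both serum XX lines also held Y-linked RNA, which XX cells cannot make (lines 17 and 46: Ddx3y 0.673 and 0.709, Eif2s3y 1.37 and 1.64 RPKM; both listed at 0 in all XX lines of the other media), so RNA of other cells was present in these libraries, while the type of those cells is not shown by Y-linked genes. The same admixture was weighed as the cause of the fall of ERK pathway targets from serum to 2i. After subtraction their median was still −1.21. The subtraction left part of the fibroblast signal, since 5 of 9 fibroblast genes still fell, so it cannot exclude admixture by itself. In the MSM cross, where the S lines held 0.442% and 1.32%, the ERK median was −1.10. This argues against admixture as the whole cause. No biological explanation of the fibroblast transcripts was tested.

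Cdkn1c, Phlda2, Slc22a18 and Ascl2 were lower in XX than in XY lines in 2i. A peculiarity of the 2 XX lines of the B6 cross was tested in the separate 2i lines of the MSM cross. There the mean XX minus XY difference of the 4 genes was −1.55 (Phlda2 −3.35, Slc22a18 −1.77, Ascl2 −0.57, Cdkn1c −0.52). This argues against such a peculiarity for Phlda2 and Slc22a18, which carried most of the mean. For Ascl2 it stays open, since XX line 15 (5.14 RPKM) read above both XY lines (4.85 and 3.79). Cdkn1c read low in all these lines (1.48 to 2.60 RPKM), so its difference decides little. For 3 of the 4 genes, all but Ascl2, both XX lines stood below both XY lines. Whether the whole region shifted could not be decided. The 53 neighbouring genes outside the imprinted lists had a median sex by medium difference (2i against t2i) of −0.31 (SD 0.48). This met neither the value set beforehand for a regional shift nor the range set for its absence. The −1.95 of the 4 genes cannot decide it, since they were singled out as low in these same 2i XX lines. A general fall of maternally expressed genes was left open too. Lower values in XX lines were not confined to 2i. In the MSM cross, S XX line 8 read below S XY line 12 for all 4 genes (Phlda2 77.8 against 178 RPKM, Cdkn1c 49.2 against 95.9). In B6-cross serum, whose libraries held fibroblast RNA, both XX lines read below both XY lines for Phlda2 and Cdkn1c. There the sexes overlapped for Slc22a18, and XX lines read higher for Ascl2. A loss of imprinting marks in XX lines is a hypothesis that was not tested, since methylation was not analysed here.

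Y-linked RNA was lower in the t2i XY lines of the B6 cross than in the other XY lines, with Ddx3y at 31.8% in line 2 and 53.8% in line 6. Loss of the Y chromosome from part of the cells would lower all Y-linked genes alike; the highest fraction was 1.65 and 1.80 times the lowest in lines 2 and 6, which leaves this open. XX cells in these cultures were excluded, since the X-linked median, less the autosomal median, was raised by at most 0.02 log2 units over the other XY lines. No biological explanation was tested.

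A library stood far from the others of its group in 4 of 112 tests (1 gene or measure over the lines of a medium). This is no more than the about 1 in 20 that chance gives. The groups held XX and XY lines together, so that rate is approximate. Dppa3 in t2i XY line 6 (56.3 RPKM against 31.9 to 33.1) had a gap of 0.95 of the range of its group. Dnmt3b in serum XY line 10 (93.3 RPKM against 34.4 to 40.9) had a gap of 0.89 of the range. Tet2 in serum XX line 17 (17.3 RPKM against 6.54 to 7.76) likewise had a gap of 0.89 of the range. The fibroblast share of 2i XY line 20 in the MSM cross (0.815%) had a gap of 1.0 of the range.

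The sex difference depended on the medium, by limma's test of the difference itself, for 166 genes between 2i and t2i, 648 between 2i and a2i and 1074 between 2i and serum. For Dppa3 these differences were 1.92, 2.48 and 2.46 log2 units, the first kept only without t2i XY line 2 (1.52 to 2.32). Between 2i and serum Dnmt3l differed by 1.12, a call that ended without 2i XX line 3, 2i XY line 2, 2i XY line 6, serum XY line 10 or serum XX line 46 (0.82 to 1.42). Zfp57 differed by −0.81, a call that ended without 2i XX line 4, 2i XY line 2 or serum lines XY 10, XY 16 and XX 17 (−0.88 to −0.73). Ddx3y differed by −1.34 between 2i and t2i (kept only without t2i XY line 6, −1.64 to −1.05) and by −1.18 between 2i and serum (kept only without serum XY line 16, −1.41 to −0.94), and since it is listed at 0 in the 2i and t2i XX lines these values depend on the pseudocount. In serum the XX lines read 0.673 and 0.709 RPKM of Ddx3y, RNA of other cells that makes the sex difference in serum smaller and the value of −1.18 larger in size.

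The 2i against serum effect differed between the library sets of the 2 crosses for 1544 genes, by the same kind of test; cross and any separate processing of the sets coincide. Among the checked genes these were Dnmt3b (−2.17), Prdm14 (1.24), Etv4 (−1.72), Nanog (0.96) and Igf2 (2.55). The value of Igf2 turned to −1.32 (SE 1.33, adjusted p = 0.57) after subtraction of the fibroblast share, which was estimated at 101% of its serum level in the B6 cross. The calls of Prdm14 (0.84 to 1.64) and Nanog (0.63 to 1.28) ended without S XY line 12, and that of Igf2 (2.16 to 3.02) without either S line. Etv4 kept its call in 5 of 14 fits with a library left out (−2.26 to −1.18).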

How the results depend on the processing

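Subtracting the fibroblast share and the fit on genes with under 10% of it were tests chosen after the result was seen. Under all settings but the replicate block, most values kept their direction and their side of the threshold: of the values of named genes, 1129 of 1192 did with a pseudocount of 0.1, 1072 of 1192 without a filter, 1124 of 1192 after quantile normalization, 510 of 559 after subtraction, 377 of 459 in the fits of 8 libraries, 273 of 279 without sex-linked genes, and 6832 of 7931 with a library left out. These values include checked genes that were not called. Of the called genes, 87 of 93 in 2i against serum kept their call in every fit with a library left out. It was 29 of 44 in t2i and 42 of 56 in a2i against 2i, but 2 of 19 in a2i against t2i. Most named calls ended in some such fit for the sex difference between 2i and t2i, the 2i MEF and the crosses. Over all genes, subtraction reversed 72, 78 and 67 calls for 2i, t2i and a2i against serum. Among named genes reversals were few. After quantile normalization Ddx3y in a2i against serum went to 0.00. After subtraction Flna went to 0.10 in 2i, 0.25 in t2i and 0.12 in a2i against serum, and Msn to 0.75 and 0.74 in 2i and t2i. Col5a1 went to −0.08 in the sex difference between 2i and serum. S100a4 and Col1a2 went to 0.00 and 0.05 in 2i against S of the MSM cross, and Igf2 and Cdh2 to −1.32 and −0.76 between the crosses. Subtraction lowers the serum values of genes that fibroblasts express, and the remainder was not scaled back up. Beyond that the cause was not tested.

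Counts moved by over 1.5 times in these cases, and except where fewer genes or libraries entered the fit the cause was not tested. Genes with under 10% of their serum signal from fibroblasts, fewer being tested, gave 3483, 3031 and 2488 calls for 2i, t2i and a2i against serum. A pseudocount of 0.1 gave 17 and no filter 113 calls for the 2i MEF, and no filter 40 for 2i-S against S. Subtraction gave 834 for the difference between crosses. Fits of the 8 libraries alone gave 415 for t2i against 2i, 706 for a2i against 2i and 1 for a2i against t2i. Leaving out sex-linked genes gave 623 for XX against XY in serum. An estimated correlation left 8 of 114 calls of gene lists. The mesoderm gene T, at −0.92 in 2i against serum, lost its call after quantile normalization (−0.44) and ran from −1.22 to −0.61 with a library left out, the call ending without 2i XY line 6 or serum XY line 10. The X-linked to autosomal difference of 0.92 was 0.85 among genes of at least 5 RPKM and 0.99 with a pseudocount of 0.1, and the overlap of 752 was 791 with that pseudocount.

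Line numbers shared between 2i and t2i (XX line 3, XY lines 2 and 6) were taken as a replicate block, which called 3 genes, against 15 in the same 6 libraries without the block. Of 59 values of named genes 16 kept their side of the threshold in it and 43 were weaker. The residuals of XX line 3 correlated at −0.25 and those of the XY lines at 0.00. With 2 XY lines in each medium, the values of lines 2 and 6 are the same number by construction. These values gave no sign that the numbers pair samples, and the labels give the lines a different letter in 2i (c) and t2i (t).

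With a library left out, counts ran from 5240 to 6004 for 2i against serum, 4643 to 5207 for t2i and 3892 to 4510 for a2i against serum, 569 to 904 for t2i and 1234 to 1633 for a2i against 2i, and 17 to 196 for a2i against t2i. They ran from 1965 to 2332, 1260 to 1702, 2153 to 2640 and 419 to 726 for XX against XY in 2i, t2i, a2i and serum, and from 46 to 123, 161 to 497 and 582 to 925 for the sex difference in 2i against t2i, a2i and serum. In the MSM cross they ran from 662 to 2257 for 2i against S, 0 to 106 for 2i-S against 2i, 0 to 1 for 2i-S against S and 7 to 109 for the 2i MEF, and from 699 to 1759 between the crosses. A fit with fewer libraries has fewer degrees of freedom. Relative depth of 0.77 to 1.87 sets how low a value can be told from 0, and genes near 1 RPKM are the ones most open to it.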

Other observations

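Of the tests in this part, the splits with a sex term were chosen after the result was seen.

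Whether the medium comparisons of the B6 cross could arise from any grouping of the same libraries was tested by splitting their 8 libraries in all 35 ways into groups of 4, with no sex term. For 2i, t2i and a2i against serum, 1 split of 35 (the real one) called as many genes as the real split (3765, 3752 and 2308 genes, the highest other splits calling 190, 386 and 482). For t2i against 2i the real split called 0 genes and all 35 splits called as many, for a2i against t2i likewise 0 and 35, and for a2i against 2i the real split called 9 and 2 splits called as many. In each of these the highest other split was the one by sex (2992, 3075 and 2547 genes), so the splits without a sex term followed a known structure of the samples. With sex as a covariate in 34 splits, the real split called 415 genes for t2i against 2i and 706 for a2i against 2i (the highest other splits 3 and 0), while a2i against t2i called 1, as did 4 splits in all, the real one included. By the splits written beforehand, chance remains a candidate explanation for all comparisons among 2i, t2i and a2i. With the sex term it clearly remains one for a2i against t2i. For t2i and a2i against 2i, the real split then stood far above the others. These splits still cannot exclude chance there, since they were chosen afterwards and those unequal in sex have less power to call genes.

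The gene Gm17604 that set the 2i-S library apart from the S lines also read 58.4 RPKM in t2i XY line 2 of the B6 cross and is listed at 0 in all libraries but these 3.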
